A study of Mus musculus with 15 samples.

How the data were processed

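RNA was measured in lumbar spinal cord of mice in 5 groups with 3 samples each. Per the labels, total RNA was extracted with a kit for lipid-rich tissue, its quality was read on a Bioanalyzer, and libraries were made from messenger RNA with a strand-specific kit (TruSeq Stranded). Per the submitters' processing notes, STAR 2.6.0c and the genome build GRCm38 were used. The tool that turned alignments into transcript counts, its strand setting and its annotation are not given in the sources used here.

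The authors deposited estimated counts per RefSeq transcript, 43511 in all, and 48.8 to 51.3% of the values per library were not whole numbers at a tolerance of 0.001. Transcripts that read alike share reads in such counts. The authors also deposited log2 CPM values of 26006 transcripts. From the values themselves, these transcripts are the ones with more than 1 CPM in at least 3 libraries, with 0 disagreements, and their CPM were counts over column totals only (ratio 0.9996 to 1.0005), with no other scaling. The deposited log2 values entered 1 alternative, and all main results rest on the estimated counts. Transcripts were matched by accession to the RefSeq gene table of GRCm38.p6 (43333 transcripts) or to GENCODE M21 (75), and 103 with 0.129% of counts stayed under their accession. Counts were summed per gene, with 1150 further copies of a transcript (0.142% of counts) included, and the expected counts were then rounded to whole numbers, which gave 25160 features. Positions are those of the RefSeq table on GRCm38.p6, counted from 1. Mitochondrial genome genes and the constant genes of immunoglobulins and T cell receptors were not analysed here. Genes with near-identical copies, among them H2-Q7, Tgtp1, Oas1a, C4b and Serpina3n, are uncertain, since the counting could divide their reads between copies.

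Total counts per library ran from 21580278 to 35395599. The 20 most abundant genes took 5.99 to 10.0% of counts, the most in chronic 3. Within a group, pairs of libraries differed by 5.14 to 232.5 chi-square per degree of freedom, so no library was present a second time. Where a group had no count the floor was 3 counts over the group, which covers counting error only.

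All tests were run in R 4.3.3. Genes were filtered with filterByExpr of edgeR 4.0.16, which left 16323, and scaled with TMM factors. They were fitted with the robust quasi-likelihood model over all 15 libraries with 1 mean per group and no block, so that the groups share 1 estimate of the spread. Each of 9 comparisons was adjusted by Benjamini-Hochberg with a threshold of 0.05. The standard error of a log2 fold change is its size over the square root of F. Log2 CPM values for list means and principal components (1000 most variable genes) used a prior count of 2. The change from remission to relapse was set against that from normal to first peak with an interaction contrast of the same model, which was chosen after seeing the data. Each comparison was also recomputed over the 10 splits of its 6 libraries into 3 and 3. Before the data were examined, 45 lists of genes for cell types, pathways and possible foreign tissue were fixed, and 43 had enough measured members for a test. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 387 tests, and again with an estimated correlation. The only gene in 2 lists was Ch25h. For members of a list, the count adjusted over the list alone applies Benjamini-Hochberg within the list.

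Genes named in the text follow a rule fixed at the same time as the lists. For each comparison it takes the 6 highest and 6 lowest log2 fold changes among genes past the threshold whose groups do not overlap, with a mean of at least 1 CPM in the higher group and at least 10 counts over the lower one, leaving out predicted genes and pseudogenes. It further takes up to 4 members of each list with the largest changes past the threshold, or where none passes the 2 most abundant, and 12 genes chosen as always available, of which Igkc was not analysed. The genes of the test of sensory neuron RNA, and the genes that separate relapse from all other libraries, lie outside it and were chosen after their values were seen. A few genes that the rule takes are not reported here.

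The steps were tested on simulated counts for all 15 libraries. Each gene was drawn around its mean over the 15 libraries, with 1 spread per gene shared by all groups. In the first peak libraries 200 genes were changed, 50 at each size, and the genes of 6 lists were raised 2-fold. First peak was then compared with normal. The wider spread of the relapse and chronic libraries was not simulated. On 16224 genes edgeR found 26% of 1.5-fold, 74% of 2-fold, 96% of 4-fold and 96% of 8-fold changes, with 2 false calls, 0.966% of all. Limma-voom made 1 false call, and DESeq2, on 16323 genes, 30, which is 11.9% of its calls. Camera and fry each found 6 of 6 moved lists and 0 of 20 others. The genes of these lists were drawn independently of each other. The simulation therefore cannot show how the preset correlation fares with genes that vary together.

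Alternatives fixed at that time as well were DESeq2 1.42.0, limma-voom, limma-trend on the deposited log2 CPM, RLE scaling, library size only, no filter on low counts, a filter of 1 CPM in 3 libraries, a fit of the 6 libraries compared, the replicate number as a block, a threshold of 1 on the log2 fold change, camera with an estimated correlation, fry, and leaving out each library. The mean log2 CPM of the Schwann cell list as a covariate and limma-voom with sample weights were chosen after seeing the data. No sample was left out of the main results.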

Results

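Gene expression was measured by RNA sequencing in the lumbar spinal cord of mice with experimental autoimmune encephalomyelitis (EAE), a model of multiple sclerosis. In it the immune system attacks the myelin of the central nervous system. The mice were of the non-obese diabetic (NOD) strain. The 15 libraries formed 5 groups of 3, taken from healthy mice (the normal group), at the first attack (first peak), in the recovery after it (remission), at a later attack (relapse) and in the chronic phase. Total estimated counts per library ran from 21580278 to 35395599. In all 16323 genes were tested. Levels are mean CPM (counts scaled to a common library total) ± SD over the 3 libraries of a group. Changes in brackets are log2 fold changes ± SE with 3 libraries in each group. Adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The labels do not say that the libraries of a group came from separate mice, so p-values measure the spread between these samples, which may be technical.

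Over the 1000 most variable genes, the first principal component held 83.2% of the variance and the second 6.47%. On the first component the normal libraries lay at -90.7 to -85.9, the remission libraries at -42.0 to -24.6 and the first peak libraries at 48.5 to 66.4. Relapse libraries 1, 2 and 3 lay apart, at -7.09, 46.3 and 6.98. So did chronic libraries 1, 2 and 3, at 31.3, 19.0 and 86.8. Interferon-gamma response genes had mean log2 CPM of 4.16, 6.76 and 5.53 in relapse libraries 1, 2 and 3 and 4.42, 4.36 and 7.35 in the chronic ones. The 3 libraries of each other group lay within 0.74. Schwann cell genes, markers of the nerve roots that leave the cord, were low in normal 3, relapse 1 and chronic 3, at 3.80, 3.30 and 3.11. All other libraries lay at 4.73 or above. Sensory ganglion neuron genes were at 2.68, 2.79 and 1.26 in the relapse libraries and at most 0.36 in the other 12. Skeletal muscle and fat genes were at 3.19 in remission 3, against -0.19 and 0.12 in the other remission libraries. In the normal cord 10 of 10 Schwann cell genes, 3 of 8 sensory ganglion genes and 7 of 10 muscle and fat genes reached 1 CPM.

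**Figure D1:**
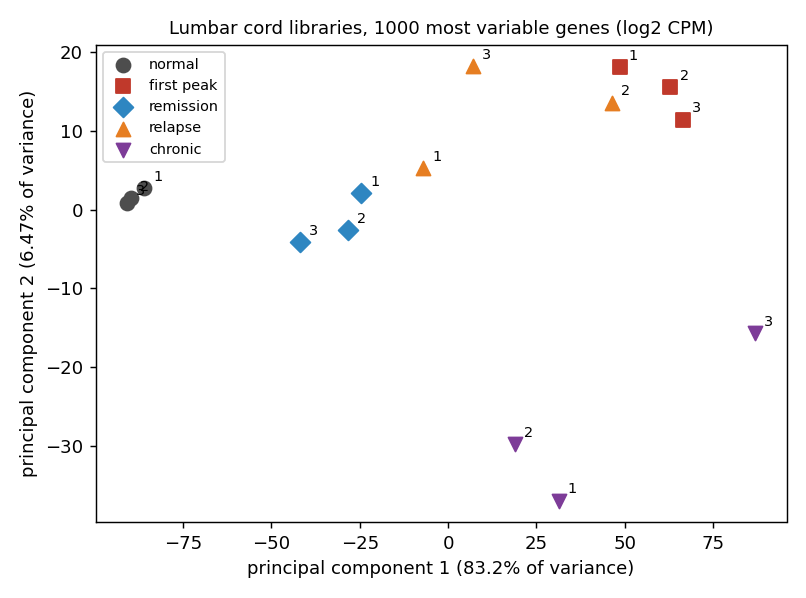
Principal components 1 and 2 of log2 CPM over the 1000 most variable genes, with the percent of variance on each axis and 1 point per library coloured by group. The 3 normal libraries lie furthest left, remission lies between normal and first peak, and the relapse and chronic libraries are spread along the first axis.

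**Figure D2:**
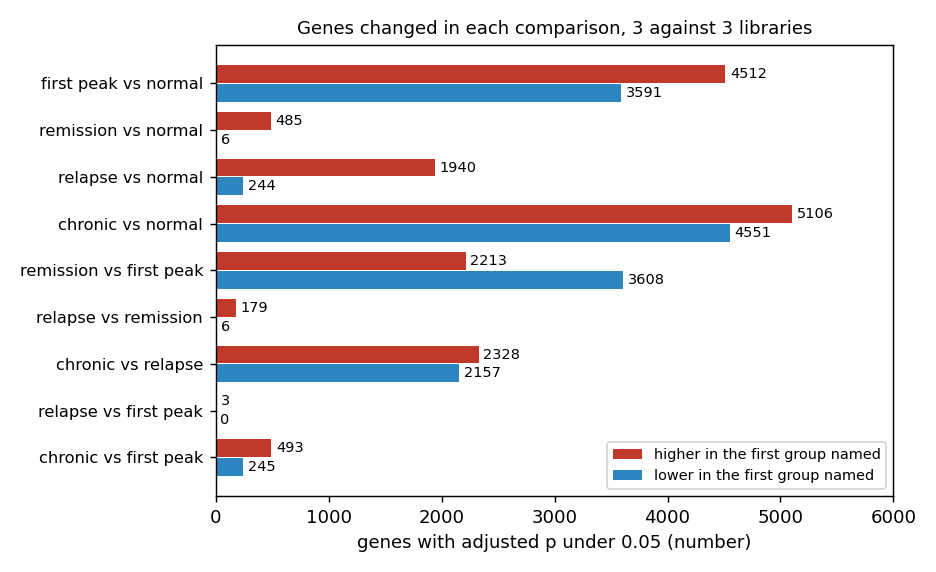
Number of genes higher and lower in the first-named group of each comparison (adjusted p under 0.05, edgeR). The bars run from 0 lower genes for relapse against first peak to 5106 higher genes for chronic against normal.

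First peak was compared with normal cord to describe the first attack. The myeloid genes Arg1, an arginine-degrading enzyme of activated macrophages, and Chil3, a chitinase-like protein, rose from 0.130 ± 0.0380 to 700.2 ± 180.4 CPM and from 1.71 ± 0.426 to 1074 ± 548 CPM. Il1rn, the interleukin-1 receptor antagonist, rose from 0.157 ± 0.105 to 130.2 ± 37.9 CPM. Cxcl10, an interferon-induced chemokine that attracts T cells, rose from 0.462 ± 0.244 to 249 ± 87.1 CPM (adjusted p of at most 0.00332 for the 4 genes). Cd74 (gene ID 16149, chromosome 18, 60803849 to 60812652), the invariant chain that guides MHC class II assembly, rose from 9.10 ± 2.55 to 1697 ± 813 CPM (7.54 ± 0.74, adjusted p = 1.47e-05). Chodl, a marker of fast motor neurons, fell from 54.4 ± 5.46 to 7.63 ± 3.16 CPM (-2.83 ± 0.62, adjusted p = 0.00313). Snap25, a synaptic vesicle fusion protein, fell from 3210.0 ± 237 to 1592 ± 240.4 CPM (-1.01 ± 0.28, adjusted p = 0.0102). Of the other genes with the largest changes, Tgm1 (9.44 ± 1.00) and Plac8 (9.43 ± 1.21) rose. Those that fell were Myoc (-4.15 ± 1.16), Notum (-3.13 ± 0.85), Clec3b (-3.11 ± 0.67) and Hcar1 (-2.74 ± 0.63).

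Higher in first peak than in normal were 14 of 14 (14 adjusted over the list alone, camera adjusted p = 1.82e-07) of the monocyte and macrophage genes, 16 of 16 (16 adjusted over the list alone, camera adjusted p = 5.91e-10) of the T cell genes and 12 of 12 (12 adjusted over the list alone, camera adjusted p = 5.78e-06) of the B cell genes. Their medians were 7.19, 6.93 (6.81 with members lacking counts in a group at their bound) and 3.77. In the normal cord 4 of those 14, 1 of 16 and 1 of 12 genes reached 1 CPM. Antigen presentation rose, with 11 of 11 (11 adjusted over the list alone, camera adjusted p = 6.74e-09) of the MHC class II genes, among them H2-Ab1 (7.96 ± 0.85) and H2-Eb1 (7.47 ± 0.74). Class I genes rose in 16 of 16 (16 adjusted over the list alone, camera adjusted p = 6.75e-12), among them the transactivator Nlrc5 (6.51 ± 0.51) and the peptide transporter Tap1 (6.39 ± 0.69). Of the genes induced by type I interferon 23 of 23 (23 adjusted over the list alone, camera adjusted p = 3.05e-17) rose, such as the nucleic acid sensor Zbp1 (8.59 ± 0.97), the antiviral synthetase Oas1a (6.14 ± 0.52) and Irf7 (6.09 ± 0.59). Interferon-gamma genes rose in 17 of 18 (17 adjusted over the list alone, camera adjusted p = 1.35e-10), with the GTPase Iigp1 at 8.90 ± 1.2. Complement rose in 16 of 16 (16 adjusted over the list alone, camera adjusted p = 6.11e-11) of its genes, including C3 (4.12 ± 0.55), Cfb (8.74 ± 1.69) and C1ra (5.32 ± 0.59). Inflammatory cytokine genes rose in 17 of 18 (17 adjusted over the list alone, camera adjusted p = 5.91e-10). Fc receptor and lysosome genes rose in 14 of 15 (15 adjusted over the list alone, camera adjusted p = 1.70e-09), with Fcgr4 (7.90 ± 0.83) and Fcgr1 (4.85 ± 0.32). All genes named here had adjusted p of at most 0.00145. In other immune lists part of the members rose. Of the dendritic cell genes 8 rose and 1 fell of 12 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00889) and of the homeostatic microglia genes 9 rose and 1 fell of 14 (9 and 1 adjusted over the list alone, camera adjusted p = 9.47e-04). Neutrophil genes rose in 11 of 14 (13 adjusted over the list alone, camera adjusted p = 8.15e-04). For these 13 lists adjusted p = 0.345 to 0.457 with an estimated correlation. The 1 lower of the dendritic cells list became 0 without normal 1, 2 or first peak 3. The 1 lower of the homeostatic microglia list became 0 without normal 1, first peak 2 or 3. The 11 higher of the neutrophil list became 7 without normal 1 or 2.

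Reactive astrocyte genes rose in 14 of 14 (14 adjusted over the list alone, camera adjusted p = 2.35e-09), with Lcn2, a lipocalin (8.38 ± 1.21), Timp1, a metalloproteinase inhibitor (8.12 ± 1.00), Serpina3n (3.85 ± 0.40) and the intermediate filament Gfap, the classical astrocyte marker (from 1599 ± 251 to 4535 ± 158 CPM). Of the homeostatic astrocyte genes 1 rose and 9 fell of 15 (1 and 9 adjusted over the list alone, camera adjusted p = 0.0139). The gap junction gene Gja1 (-1.16 ± 0.29) and Fgfr3 (-1.19 ± 0.27) were among the lower ones. Proliferation genes rose in 19 of 19 (19 adjusted over the list alone, camera adjusted p = 4.87e-09), with Mki67 from 3.27 ± 1.60 to 107 ± 27.6 CPM and Top2a at 5.02 ± 0.72. Fibroblast and matrix genes rose in 13 of 17 (14 adjusted over the list alone, camera adjusted p = 2.85e-04), with fibronectin, Fn1, from 85.0 ± 1.38 to 1500.0 ± 336 CPM. Pan-neuronal genes fell in 15 of 15 (15 adjusted over the list alone, camera adjusted p = 1.41e-05), including Nefh (-1.14 ± 0.32) and Rbfox3 (-0.96 ± 0.21). Inhibitory transmission genes fell in 10 of 13 (12 adjusted over the list alone, camera adjusted p = 7.08e-04), including Gad1 (-0.76 ± 0.15) and Slc32a1 (-0.89 ± 0.22). Of the motor neuron genes 1 rose and 8 fell of 12 (1 and 8 adjusted over the list alone, camera adjusted p = 0.00177). The lower ones included the choline transporter Slc5a7 (-1.80 ± 0.41), the vesicular acetylcholine transporter Slc18a3 (-1.55 ± 0.38) and the acetylcholine-synthesising enzyme Chat (-1.46 ± 0.39). Ion channel genes fell in 11 of 16 (13 adjusted over the list alone, camera adjusted p = 2.85e-04). Of the mature oligodendrocyte genes 2 rose and 7 fell of 19 (2 and 7 adjusted over the list alone, camera adjusted p = 0.0888). These neuronal and glial markers sat beside Schwann cell genes in which 2 rose and 0 fell of 10 (1 and 0 adjusted over the list alone, camera adjusted p = 0.555). In sensory ganglion genes 0 rose and 2 fell of 8 (0 and 2 adjusted over the list alone, camera adjusted p = 0.156). For these 11 lists adjusted p = 0.345 to 0.885 with an estimated correlation. The 10 lower of the inhibitory transmission list became 5 without normal 1 or first peak 2, 4 without normal 2 or first peak 3 and 6 without normal 3. The 1 higher of the motor neuron list became 0 without normal 3 or first peak 2. The 11 lower of the ion channel list became 3 without normal 3 and 6 without first peak 3. The 2 higher of the Schwann cell list became 1 without normal 1, 3, first peak 1 or 2. Skeletal muscle and fat genes, with 1 of 10 lower, had a median of -2.26 (camera adjusted p = 0.0454). That camera call ended without first peak 1 (adjusted p = 0.102) or normal 2 (adjusted p = 0.0977).

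In all, 8103 genes differed between first peak and normal, 4512 higher and 3591 lower, and 2934 of them by at least 2-fold. The groups did not overlap for 66.1% of genes tested, against 10% by chance. Of the 43 lists 26 rose and 8 fell by camera with a preset correlation, and 0 with an estimated one.

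Remission was compared with first peak and with normal to describe recovery from the first attack. Against first peak, Arg1 fell from 700.2 ± 180.4 to 0.403 ± 0.159 CPM, the acute-phase gene Saa3 from 234 ± 165 to 2.10 ± 0.720 CPM. Lower too was Acod1, an enzyme of activated macrophages, from 75.2 ± 24.7 to 0.680 ± 0.171 CPM (adjusted p of at most 0.00394). Cd74 fell from 1697 ± 813 to 250.1 ± 76.6 CPM (-2.76 ± 0.59, adjusted p = 0.00457). The microglial growth factor receptor Csf1r fell from 824 ± 168 to 278 ± 11.6 CPM (-1.56 ± 0.30, adjusted p = 0.00297). Gja1 rose from 208 ± 49.9 to 529 ± 18.1 CPM (1.35 ± 0.29, adjusted p = 0.00502). The glutamate transporter Slc1a2 of astrocytes rose from 2016 ± 413 to 4161 ± 322 CPM (1.05 ± 0.26, adjusted p = 0.00972).

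Both interferon lists fell. Lower were 23 of 23 (23 adjusted over the list alone, camera adjusted p = 1.07e-16) of the type I genes, with Zbp1 (-5.00 ± 0.74) and Isg15 (-3.97 ± 0.48). Of the interferon-gamma genes 17 of 18 (18 adjusted over the list alone, camera adjusted p = 1.02e-09) fell, with Igtp (-4.98 ± 0.95) and Iigp1 (-4.91 ± 0.98). Also lower were 16 of 16 (16 adjusted over the list alone, camera adjusted p = 8.44e-07) of the T cell genes and 11 of 11 (11 adjusted over the list alone, camera adjusted p = 4.49e-06) of the MHC class II genes. Class I genes fell in 16 of 16 (16 adjusted over the list alone, camera adjusted p = 3.58e-09) and complement genes in 16 of 16 (16 adjusted over the list alone, camera adjusted p = 3.24e-08), C3 among them (-2.10 ± 0.50). Fc receptor and lysosome genes fell in 14 of 15 (14 adjusted over the list alone, camera adjusted p = 2.86e-08), such as Fcgr2b (-4.53 ± 0.76). Reactive astrocyte genes fell in 13 of 14 (14 adjusted over the list alone, camera adjusted p = 4.30e-08), such as Lcn2 (-4.63 ± 0.99), Timp1 (-5.09 ± 0.82) and Serpina3n (-3.03 ± 0.38). Proliferation genes fell in 19 of 19 (19 adjusted over the list alone, camera adjusted p = 4.64e-10), with Mki67 (-3.73 ± 0.83) and Top2a (-3.75 ± 0.66). For these 9 lists adjusted p = 0.345 to 0.401 with an estimated correlation. Of the homeostatic astrocyte genes 9 rose and 1 fell of 15 (11 and 1 adjusted over the list alone, camera adjusted p = 5.08e-04). Pan-neuronal genes differed too: 7 rose and 0 fell of 15 (12 and 0 adjusted over the list alone, camera adjusted p = 8.38e-05), with the splicing factor Rbfox3 at 0.79 ± 0.21 (adjusted p = 0.457 to 0.463 with an estimated correlation). Fibroblast and matrix genes fell in 7 of 17 (7 adjusted over the list alone, camera adjusted p = 0.0174), with Fn1 at -2.92 ± 0.63 (adjusted p = 0.547 with an estimated correlation). Skeletal muscle and fat genes were higher in 8 of 10 (9 adjusted over the list alone, camera adjusted p = 0.00354), with remission 3 as the highest library by far (adjusted p = 0.429 with an estimated correlation). The 7 higher of the pan-neuronal list became 2 without first peak 3 or remission 2 and 3 without remission 3. The 7 lower of the fibroblast and matrix list became 2 without first peak 2, remission 2 or 3 and 3 without first peak 3 or remission 1. The 8 higher of the skeletal muscle and fat list became 2 without first peak 1 and 0 without first peak 3 or remission 3.

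Remission and first peak differed in 5821 genes, 2213 higher and 3608 lower in remission, 2189 of them by at least 2-fold. The groups did not overlap for 62.2% of genes tested against 10% by chance. Of the 43 lists 7 rose and 24 fell by camera, 0 with an estimated correlation. The camera call ended for the fibroblast and matrix list without first peak 2 (adjusted p = 0.0574). Without remission 2 or 3 the count of genes was 3777 and 3380, of which 1175 and 898 were higher. On the 6 libraries alone 3729 were higher. With limma-voom and library weights, an alternative added after the counts were seen, 9773 genes were called, 4580 of them higher.

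Against the normal cord, genes of antigen presentation were higher in remission. Cd74 rose from 9.10 ± 2.55 to 250.1 ± 76.6 CPM (4.78 ± 0.65, adjusted p = 0.00367), and the class I gene H2-Q7 by 4.84 ± 0.72. Higher too was Jchain (gene ID 16069, chromosome 5, 88519809 to 88527897), which links antibody units in plasma cells, from 0.758 ± 0.0802 to 16.1 ± 5.90 CPM (4.42 ± 0.47, adjusted p = 9.34e-04). C4b, of the classical complement pathway, and Cxcl12, a stromal chemokine, were higher by 2.03 ± 0.24 and 1.34 ± 0.16. So were the interferon gene Ifi44 (3.08 ± 0.34), the cytokine receptors Csf3r (2.14 ± 0.25) and Osmr (1.91 ± 0.17). The same holds for the Fc receptor Fcgr1 (1.93 ± 0.29), the cholesterol hydroxylase Ch25h (3.60 ± 0.40) and the endothelial receptor Flt1 (1.2 ± 0.15). These genes had adjusted p of at most 0.00540. Genes that did not pass the test were Snap25 at -0.32 ± 0.28, Mbp, the major myelin protein, at -0.15 ± 0.26, the water channel Aqp4 of astrocytes at 0.60 ± 0.23, and the microglial receptor P2ry12 at 0.11 ± 0.11.

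In remission against normal, MHC class II genes rose in 7 of 11 (10 adjusted over the list alone, camera adjusted p = 8.81e-15) and class I genes in 11 of 16 (13 adjusted over the list alone, camera adjusted p = 9.48e-17). Type I interferon genes rose in 12 of 23 (20 adjusted over the list alone, camera adjusted p = 4.27e-19) and complement genes in 11 of 16 (15 adjusted over the list alone, camera adjusted p = 2.37e-15). Fc receptor and lysosome genes rose in 5 of 15 (11 adjusted over the list alone, camera adjusted p = 3.79e-10) and B cell genes in 5 of 12 (9 adjusted over the list alone, camera adjusted p = 7.05e-10). For these 6 lists adjusted p = 0.345 with an estimated correlation. The 7 higher of the MHC class II list became 4 without normal 1 or 2 and 3 without normal 3. The 11 higher of the MHC class I list became 6 without normal 1, 5 without normal 2 or 3 and 7 without remission 1 or 2. The 12 higher of the type I interferon list became 4 without normal 1, 3 without normal 2 or 3 and 6 without remission 2. The 11 higher of the complement list became 4 to 6 without any of the 6 libraries. The 5 higher of the Fc receptor and lysosome list became 1 without normal 1, 2 or 3 and 3 without remission 1 or 2. The 5 higher of the B cell list became 1 without normal 1, 3 or remission 2, 0 without normal 2 and 2 without remission 1. The comparison gave 491 genes, 485 higher and 6 lower, with 381 at least 2-fold apart. At an unadjusted p under 0.05 there were 2456. Groups did not overlap for 43.4% of genes against 10% by chance. Leaving out any of the 6 libraries lowered the count to between 99 and 265. The spread was pooled over all 15 libraries, of which relapse and chronic varied most. With only the 6 libraries compared 4343 genes passed, with DESeq2 1205, with limma-voom 167, and with limma-trend on the deposited log2 CPM 875. Library weights, chosen after the counts were seen, gave 4559. The 6 lower genes became 0 to 1 without any 1 library, 2 with limma-voom, 3 with the replicate block, 93 with DESeq2, 1754 on the 6 libraries alone and 1856 with library weights. Camera moved 26 lists up and 4 down, 0 with an estimated correlation. Among the 4 was the mature oligodendrocyte list (camera adjusted p = 0.00808), although 0 of its 19 genes passed alone. Without normal 3 that camera call ended (adjusted p = 0.0848).

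Relapse was set against normal, remission and first peak to describe the second attack. Against normal, Il1rn rose from 0.157 ± 0.105 to 68.7 ± 58.0 CPM (8.70 ± 1.5, adjusted p = 0.00190) and the macrophage elastase Mmp12 from 0.134 ± 0.0848 to 31.5 ± 41.0 CPM (7.92 ± 1.58, adjusted p = 0.00473). Cd74 rose from 9.10 ± 2.55 to 530.2 ± 390.4 CPM (5.86 ± 0.68, adjusted p = 1.59e-04). Timp1 rose from 0.726 ± 0.0733 to 72.2 ± 53.8 CPM, Serpina3n from 115 ± 6.22 to 1016 ± 188 CPM and Gfap from 1599 ± 251 to 4771 ± 1721 CPM (adjusted p of at most 6.47e-04). The neuropeptide genes Uts2 and Uts2b and the receptor Vipr2 fell, by -2.42 ± 0.24, -1.80 ± 0.39 and -1.87 ± 0.30. So did Car3, a carbonic anhydrase (-2.73 ± 0.54), and the transcription factor Zbtb20 (-1.82 ± 0.34).

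Higher in relapse than in normal were 15 of 16 (16 adjusted over the list alone, camera adjusted p = 3.15e-13) of the T cell genes. MHC class II genes rose in 11 of 11 (11 adjusted over the list alone, camera adjusted p = 4.55e-12) and class I genes in 15 of 16 (16 adjusted over the list alone, camera adjusted p = 3.01e-15), with H2-Ab1 (6.06 ± 0.79) and Nlrc5 (5.36 ± 0.49). Type I interferon genes rose in 23 of 23 (23 adjusted over the list alone, camera adjusted p = 3.58e-27), with Usp18 (4.91 ± 0.40), Zbp1 (7.17 ± 0.95) and Oas2 (4.95 ± 0.63). Interferon-gamma genes rose in 17 of 18 (17 adjusted over the list alone, camera adjusted p = 7.21e-14), with Iigp1 (7.03 ± 1.12) and Tgtp1 (6.72 ± 1.41). Complement rose in 15 of 16 (16 adjusted over the list alone, camera adjusted p = 8.81e-15), with C1ra (3.84 ± 0.56), Itgb2 (3.75 ± 0.54) and C3 (2.84 ± 0.52), and chemokines in 12 of 14 (12 adjusted over the list alone, camera adjusted p = 2.06e-10), with Cxcl10 (7.43 ± 1.10) and Ccl2 (6.36 ± 1.02). Inflammatory cytokines rose in 16 of 18 (16 adjusted over the list alone, camera adjusted p = 5.99e-15) and reactive astrocyte genes in 13 of 14 (14 adjusted over the list alone, camera adjusted p = 8.81e-15), with Lcn2 (6.14 ± 1.12). In the normal cord 1 of the 16 T cell genes and 3 of the 14 chemokines reached 1 CPM. For these 9 lists adjusted p = 0.345 with an estimated correlation. Of the sensory ganglion genes 5 rose and 1 fell of 8 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0106), with the sodium channel Scn11a at 4.51 ± 0.61 and the actin-binding protein Avil at 4.43 ± 0.80. In Schwann cell genes 1 rose and 0 fell of 10 (1 and 0 adjusted over the list alone, camera adjusted p = 0.877). For these lists adjusted p = 0.369 to 0.976 with an estimated correlation. Pan-neuronal genes fell in 2 of 15 (2 adjusted over the list alone, camera adjusted p = 5.90e-05), and proliferation genes rose in 18 of 19 (19 adjusted over the list alone, camera adjusted p = 4.89e-10). For this pair of lists adjusted p = 0.369 to 0.456 with an estimated correlation. The 5 higher of the sensory ganglion list became 3 without normal 1, 2, 3, relapse 1 or 2. The 1 lower of the sensory ganglion list became 0 without normal 1, 2, 3, relapse 1 or 3. The 1 higher of the Schwann cell list became 0 without normal 1, 3 or relapse 2. The 2 lower of the pan-neuronal list became 0 without normal 1, 2 or relapse 2 and 1 without normal 3 or relapse 1. The 18 higher of the cell cycle list became 9 without normal 1 or 2, 7 without normal 3 and 6 without relapse 2.

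Against normal 2184 genes differed in relapse, 1940 higher and 244 lower, 1522 of them by at least 2-fold. Groups did not overlap for 39.0% of genes against 10% by chance. Library weights, added after the counts were seen, gave 4343 genes. Without normal 1, 2 or 3 the count was 1325, 1320 and 1323, and without relapse 2 it was 1262. The 244 lower genes became 40, 51 and 71 without normal 1, 2 or 3, 491 without relapse 1 and 32 without relapse 2. They were 92 with library size only, 94 with limma-trend, 138 with the replicate block, 484 with DESeq2 and 476 on the 6 libraries alone. Of the settings added after the counts were seen, library weights gave 1506 lower and the Schwann cell covariate 390. By camera 27 lists rose and 7 fell, 0 with an estimated correlation.

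From remission to relapse few genes passed the test. The chemokine Ccl12 rose from 3.78 ± 0.309 to 26.6 ± 6.19 CPM (2.82 ± 0.21, adjusted p = 9.25e-05), and this call held without any 1 library. Scn10a (gene ID 20264, chromosome 9, 119608456 to 119719322), a sodium channel of pain-sensing neurons, stood at 8.80 ± 6.08 CPM in relapse and had no count in remission (adjusted p = 0.00553). Scn11a rose from 0.0854 ± 0.0209 to 4.76 ± 3.17 CPM (5.72 ± 0.68, adjusted p = 0.00335). The interferon-induced protease Usp18 rose from 5.50 ± 1.08 to 28.7 ± 5.42 CPM (2.38 ± 0.34, adjusted p = 0.00973) and Serpina3n from 203 ± 18.3 to 1016 ± 188 CPM (2.32 ± 0.37, adjusted p = 0.0142). The immediate early gene Junb rose from 9.07 ± 1.61 to 31.5 ± 6.28 CPM (1.80 ± 0.27, adjusted p = 0.0103). Cd74, at 1.08 ± 0.56, Cd22 of B cells, at 0.53 ± 0.52, Mki67, at 2.31 ± 0.79, and the B cell chemokine Cxcl13, at 2.29 ± 0.65, did not pass. The call ended for Junb without remission 1, 2 or 3 (adjusted p = 0.0508 to 0.0807), Serpina3n without remission 1, 2 or 3 (adjusted p = 0.0858 to 0.0977) and Usp18 without remission 2 or 3 (adjusted p = 0.0708 to 0.0746).

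Type I interferon genes rose from remission to relapse in 17 of 23 (23 adjusted over the list alone, camera adjusted p = 2.57e-31), and chemokines in 5 of 14 (11 adjusted over the list alone, camera adjusted p = 7.05e-10). Reactive astrocyte genes rose in 7 of 14 (14 adjusted over the list alone, camera adjusted p = 1.15e-16), beside sensory ganglion genes in 3 of 8 (5 adjusted over the list alone, camera adjusted p = 5.66e-07). For these 4 lists adjusted p = 0.345 with an estimated correlation. No member passed over all genes in the interferon-gamma, T cell, MHC class II and cell cycle lists. Adjusted over the list alone 16 of 18, 0 of 16, 0 of 11 and 19 of 19 were higher in that order, with camera adjusted p of 4.55e-12, 4.11e-05, 2.51e-04 and 1.60e-14 (adjusted p = 0.345 to 0.456 with an estimated correlation). None passed either in the B cell and neutrophil lists, with 0 of 12 and 0 of 14 higher adjusted over the list alone, and camera did not call them (adjusted p = 0.521 and 0.578). The 17 higher of the type I interferon list became 4 without remission 1, 2 without remission 2 or 3, 5 without relapse 2 and 11 without relapse 3. The 5 higher of the chemokine list became 1 to 8 without any of the 6 libraries. The 7 higher of the reactive astrocyte list became 1 without remission 1 or 2 and 0 without remission 3. The 3 higher of the sensory ganglion list became 5 without relapse 3. The 0 higher of the interferon-gamma list became 4 without relapse 1. Of the skeletal muscle and fat genes 0 rose and 0 fell of 10 (0 and 9 adjusted over the list alone, camera adjusted p = 9.06e-06), with a median of -3.32 (adjusted p = 0.345 with an estimated correlation). The comparison gave 185 genes, 179 higher and 6 lower, 156 of them at least 2-fold apart. At an unadjusted p under 0.05 there were 2108. Groups did not overlap for 22.8% of genes, against 10% by chance. Without remission 1, 2 or 3 the count was 20, 11 and 14, and without relapse 2 it was 50. The 6 lower genes became 0 to 2 without these libraries, 19 without relapse 1 and 32 on the 6 libraries alone. With the replicate block the count was 106, 3 of them lower. DESeq2 called 718 genes, 66 of them lower, limma-voom 71, 3 of them lower, and library weights, added after the counts were seen, 1268, with 155 lower. Camera called 24 lists higher and 7 lower, 0 with an estimated correlation. The directional test fry called 10.

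Between relapse and first peak 3 genes passed, all higher in relapse. The potassium channel subunit Abcc9 rose from 14.7 ± 1.97 to 27.8 ± 1.07 CPM (0.92 ± 0.11, adjusted p = 0.0156) and Scn11a from 0.133 ± 0.0808 to 4.76 ± 3.17 CPM (5.12 ± 0.66, adjusted p = 0.0234). Scn10a stood at 8.80 ± 6.08 CPM against 1 count in first peak (adjusted p = 0.0291). The call ended for Abcc9 without first peak 1, 3 or relapse 1 (adjusted p = 0.0930 to 0.10), Scn10a without first peak 1, 2, 3 or relapse 1 (adjusted p = 0.0945 to 0.260) and Scn11a without first peak 1, 2, 3 or relapse 1 (adjusted p = 0.0945 to 0.201). Cd74 stood at 530.2 ± 390.4 CPM in relapse and 1697 ± 813 in first peak (-1.68 ± 0.56, adjusted p = 0.12). Csf1r was at -1.08 ± 0.30, Iigp1 at -1.86 ± 0.85, Slc1a2 at 0.80 ± 0.26 and Cxcl13 at 0.21 ± 0.61, none past the threshold.

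By camera the T cell, antigen presentation and interferon lists were lower in relapse than in first peak, although no member of them passed alone. The T cell list had a median of -1.43 (camera adjusted p = 6.42e-06), MHC class II -1.61 (3.93e-06) and class I -1.52 (1.11e-09). The medians of the interferon lists were type I interferon -1.02 (4.34e-08) and interferon-gamma -1.69 (8.97e-07). Adjusted over the list alone, the numbers lower were 0 of 16, 9 of 11, 16 of 16, 19 of 23 and 0 of 18 in that order. Not every immune list was called. The chemokine list had a median of -0.04, a mean of -0.34 and a test direction of up (camera adjusted p = 0.951). The dendritic cell, plasma cell and T cell inhibitory receptor lists, with medians of -0.83, -0.33 and -0.93, had camera adjusted p of 0.119, 0.684 and 0.0556. The pan-neuronal list was higher, with a median of 0.33 and 0 of 15 higher adjusted over the list alone (4.45e-04). Sensory ganglion genes rose in 2 of 8 (6 adjusted over the list alone, camera adjusted p = 2.95e-08). For these 7 lists adjusted p = 0.345 to 0.486 with an estimated correlation. Without relapse 2 the members called lower over all genes were 7 of the T cell list, 8 of MHC class II, 14 of class I, 5 of type I interferon and 1 of interferon-gamma. The 0 lower of the T cell inhibitory receptors and ligands list became 2 without relapse 2. The 2 higher of the sensory ganglion list became 0 to 4 without any of the 6 libraries. At an unadjusted p under 0.05 there were 4183 genes. Groups did not overlap for 32.3% of genes against 10% by chance. Leaving out relapse 2 gave 1229 genes, 376 higher and 853 lower, leaving out relapse 3 gave 14 and leaving out first peak 2 gave 1. Without first peak 1, first peak 3 or relapse 1 edgeR called 0, with 2684 to 4281 at an unadjusted p under 0.05. DESeq2 called 1421 genes, 368 higher and 1053 lower, limma-voom 1 and edgeR without the low-count filter 5. On the 6 libraries alone edgeR called 0, with 3846 at an unadjusted p under 0.05. Added after the counts were seen, a Schwann cell covariate gave 893 genes, 158 higher and 735 lower, and library weights 1489, 283 higher and 1206 lower. Camera put 8 lists higher and 19 lower, 0 with an estimated correlation. Fry called 6.

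The chronic group was set against normal, relapse and first peak to describe the late disease. Against normal, Gpnmb (gene ID 93695, chromosome 6, 49036518 to 49058182), a glycoprotein of lipid-loaded phagocytes, rose from 2.35 ± 0.867 to 1718 ± 936 CPM (9.52 ± 0.93, adjusted p = 9.42e-06). The lysozyme Lyz2 rose from 29.8 ± 1.33 to 7272 ± 3471 CPM (7.93 ± 0.83, adjusted p = 1.43e-05) and Cd74 from 9.10 ± 2.55 to 2437 ± 1733 CPM (8.06 ± 0.75, adjusted p = 7.11e-06). Hmgcs1 (gene ID 208715, chromosome 13, 119690351 to 119708260), an early enzyme of cholesterol synthesis, fell from 628 ± 10.1 to 205 ± 34.1 CPM (-1.62 ± 0.18, adjusted p = 2.31e-05). Snap25 fell from 3210.0 ± 237 to 1060.0 ± 478 CPM (-1.60 ± 0.28, adjusted p = 4.74e-04) and Mbp from 14150.0 ± 1014 to 7922 ± 1907 CPM (-0.84 ± 0.26, adjusted p = 0.0141). The collagen Col3a1 rose from 59.0 ± 24.6 to 699.7 ± 350.5 CPM and the matrix protein Postn from 4.24 ± 1.35 to 79.2 ± 36 CPM (adjusted p of at most 4.04e-04).

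Disease-associated microglia genes rose in chronic cord against normal in 20 of 21 (20 adjusted over the list alone, camera adjusted p = 5.91e-10). Foam cell genes rose in 16 of 16 (16 adjusted over the list alone, camera adjusted p = 5.67e-08), with Lgals3 at 7.65 ± 0.89 and the scavenger receptor Msr1 at 6.97 ± 0.66. Fc receptor and lysosome genes rose in 15 of 15 (15 adjusted over the list alone, camera adjusted p = 1.21e-09). Complement rose in 16 of 16 (16 adjusted over the list alone, camera adjusted p = 6.31e-10), with C3 (4.87 ± 0.57) and C3ar1 (5.09 ± 0.38), and MHC class II in 11 of 11 (11 adjusted over the list alone, camera adjusted p = 1.20e-07), with H2-Ab1 at 8.16 ± 0.86. Fibroblast and matrix genes rose in 17 of 17 (17 adjusted over the list alone, camera adjusted p = 1.91e-07), with Fn1 at 4.87 ± 0.69. Of the type I interferon genes 22 rose and 1 fell of 23 (22 and 1 adjusted over the list alone, camera adjusted p = 1.97e-09). Axon injury genes rose in 7 of 11 (7 adjusted over the list alone, camera adjusted p = 0.0128), with the transcription factor Atf3 at 5.51 ± 0.39 and the neuropeptide Gal at 2.25 ± 0.27. In the normal cord 20 of the 21 microglia, 13 of the 16 foam cell and 17 of the 17 fibroblast and matrix genes reached 1 CPM. For these 8 lists adjusted p = 0.345 to 0.369 with an estimated correlation. The 1 lower of the type I interferon list became 0 without normal 1, 2 or chronic 1.

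Cholesterol synthesis genes fell in 23 of 24 (23 adjusted over the list alone, camera adjusted p = 1.00e-09), with Idi1 (-1.70 ± 0.20) and Cyp51 (-1.69 ± 0.17). Pan-neuronal genes fell in 15 of 15 (15 adjusted over the list alone, camera adjusted p = 1.73e-06), with the neurofilaments Nefm (-1.47 ± 0.33), Nefh (-1.44 ± 0.33) and Nefl (-1.36 ± 0.28). Inhibitory transmission genes fell in 13 of 13 (13 adjusted over the list alone, camera adjusted p = 1.43e-05), with the glycine receptor Glra1 at -1.28 ± 0.28. Glutamatergic genes fell in 12 of 14 (13 adjusted over the list alone, camera adjusted p = 1.10e-04), with Grin2a (-1.46 ± 0.23) and Slc17a6 (-1.28 ± 0.22). Ion channel genes fell in 16 of 16 (16 adjusted over the list alone, camera adjusted p = 4.31e-06), with Scn1a at -1.46 ± 0.30. Of the mature oligodendrocyte genes 1 rose and 13 fell of 19 (1 and 13 adjusted over the list alone, camera adjusted p = 9.40e-04), with Fa2h at -1.13 ± 0.20. Nuclear genes of oxidative phosphorylation fell in 17 of 19 (17 adjusted over the list alone, camera adjusted p = 2.46e-06), with Ndufb8 at -0.65 ± 0.10. In Schwann cell genes 1 rose and 0 fell of 10 (1 and 0 adjusted over the list alone, camera adjusted p = 0.769). In sensory ganglion genes 1 rose and 2 fell of 8 (1 and 2 adjusted over the list alone, camera adjusted p = 0.310). For these lists adjusted p = 0.345 to 0.946 with an estimated correlation. The Schwann cell list had a median of -0.25, a mean of 0.11 and a test direction of down. The 1 higher of the sensory ganglion list became 0 without chronic 3. The 2 lower of the sensory ganglion list became 1 without normal 3. Of the skeletal muscle and fat genes 1 rose and 4 fell of 10, and of the red blood cell genes 0 rose and 3 fell of 6. Leaving out 1 library gave 0 to 4 and 0 to 3 lower in these 2 lists.

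Chronic and normal cord differed in 9657 genes, 5106 higher and 4551 lower, 4029 of them by at least 2-fold. The groups did not overlap for 68.6% of genes tested, against 10% by chance. Camera moved 25 lists up and 8 down, 0 with an estimated correlation.

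Against relapse, Gpnmb rose from 41.8 ± 38.6 to 1718 ± 936 CPM (5.36 ± 0.76, adjusted p = 0.00105) and the proton pump subunit Atp6v0d2 from 5.13 ± 7.89 to 168 ± 96.8 CPM (5.04 ± 1.11, adjusted p = 0.00982). The lipid-binding genes Fabp4, Apoc4 and Apoc1 rose by 4.92 ± 0.60, 4.66 ± 0.52 and 3.06 ± 0.31. The B cell inhibitory receptor Cd22 rose from 6.34 ± 4.34 to 76.5 ± 21.9 CPM (3.59 ± 0.54, adjusted p = 0.00137) and Atf3 from 13.7 ± 6.06 to 62.2 ± 17.8 CPM (2.19 ± 0.32, adjusted p = 0.00121). Hmgcs1 fell from 588 ± 40.9 to 205 ± 34.1 CPM (-1.52 ± 0.18, adjusted p = 4.50e-04). The myelin lipid enzyme Fa2h fell from 178 ± 58.8 to 90.6 ± 19.0 CPM (-0.98 ± 0.20, adjusted p = 0.00623) and Glra1 from 136 ± 11.5 to 57.6 ± 27.6 CPM (-1.24 ± 0.28, adjusted p = 0.0108). Scn11a stood at 0.0807 ± 0.0381 CPM against 4.76 ± 3.17 in relapse (-5.78 ± 0.70, adjusted p = 4.39e-04).

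Disease-associated microglia genes rose from relapse to chronic in 17 of 21 (18 adjusted over the list alone, camera adjusted p = 1.03e-11), with Lpl (3.91 ± 0.53) and Itgax (3.56 ± 0.58). Foam cell genes rose in 12 of 16 (12 adjusted over the list alone, camera adjusted p = 4.18e-08), with the cholesterol exporter Abca1 at 2.58 ± 0.31. Fc receptor and lysosome genes rose in 12 of 15 (14 adjusted over the list alone, camera adjusted p = 2.05e-08), with Cd84 (2.73 ± 0.42), Hexa (2.40 ± 0.30) and Ctsz (2.13 ± 0.33). Complement genes rose in 10 of 16 (15 adjusted over the list alone, camera adjusted p = 6.41e-07), with C3ar1 (2.16 ± 0.33) and C1qa (1.76 ± 0.30). Axon injury genes rose in 6 of 11 (6 adjusted over the list alone, camera adjusted p = 6.93e-04), with Gal (2.04 ± 0.27), Ecel1 (1.16 ± 0.23) and Sprr1a (4.03 ± 0.70). B cell genes rose in 6 of 12 (11 adjusted over the list alone, camera adjusted p = 2.31e-05). Fibroblast and matrix genes rose in 13 of 17 (14 adjusted over the list alone, camera adjusted p = 8.34e-09), with Postn (3.48 ± 0.38) and Mmp2 (2.10 ± 0.25). For these 7 lists adjusted p = 0.345 to 0.369 with an estimated correlation. Cholesterol synthesis genes fell in 22 of 24 (23 adjusted over the list alone, camera adjusted p = 4.81e-17), with Idi1 (-1.65 ± 0.20) and Cyp51 (-1.62 ± 0.17). Mature oligodendrocyte genes fell in 8 of 19 (9 adjusted over the list alone, camera adjusted p = 4.74e-05), with Mobp (-0.88 ± 0.18) and Mal (-0.78 ± 0.14). Pan-neuronal genes fell in 10 of 15 (12 adjusted over the list alone, camera adjusted p = 5.29e-06) and ion channel genes in 12 of 16 (14 adjusted over the list alone, camera adjusted p = 3.69e-07). Sensory ganglion genes fell in 5 of 8 (6 adjusted over the list alone, camera adjusted p = 2.03e-04). For these 5 lists adjusted p = 0.345 to 0.426 with an estimated correlation. Of the type I interferon genes 0 rose and 5 fell of 23 (0 and 5 adjusted over the list alone, camera adjusted p = 0.00127), with Mx2 at -1.12 ± 0.21 (adjusted p = 0.547 with an estimated correlation). The 6 higher of the B cell list became 3 without relapse 1. The 13 higher of the fibroblast and matrix list became 8 without relapse 3. The 8 lower of the mature oligodendrocyte list became 3 without relapse 1, 4 without relapse 3 and 5 without chronic 2 or 3. The 10 lower of the pan-neuronal list became 5 without relapse 1 or chronic 1 and 0 without relapse 3. The 12 lower of the ion channel list became 2 without relapse 3. The 5 lower of the sensory ganglion list became 3 without relapse 1 or 2. The 5 lower of the type I interferon list became 2 without relapse 3 or chronic 1, 3 without chronic 2 and 16 without chronic 3.

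Chronic and relapse differed in 4485 genes, 2328 higher and 2157 lower, 1201 of them at least 2-fold apart. Groups did not overlap for 33.7% of genes, against 10% by chance. The relapse and chronic libraries varied most, and with a spread estimated from these 6 libraries alone 59 genes passed. Without relapse 3 the count was 1708, 1092 higher and 616 lower, and without chronic 3 it was 2801, 1454 higher and 1347 lower. By camera 12 lists rose and 10 fell, 0 with an estimated correlation. The camera call ended for the type I interferon list without chronic 2 (adjusted p = 0.0509).

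Against first peak, the chronic group had higher Gpnmb, from 80.3 ± 61.2 to 1718 ± 936 CPM (4.42 ± 0.72, adjusted p = 0.00477), and higher lipoprotein lipase Lpl, from 17.7 ± 1.62 to 206 ± 154 CPM (3.54 ± 0.52, adjusted p = 0.00235). Apoe, the main lipid carrier of the central nervous system, rose from 984 ± 486 to 6266 ± 2322 CPM (2.67 ± 0.35, adjusted p = 0.00105). The cholesterol exporters Abca1 and Abcg1 were higher by 1.92 ± 0.30 and 1.77 ± 0.15, and Mylip, which degrades the LDL receptor, by 1.72 ± 0.22. Isg15 fell from 60.9 ± 10.6 to 12.1 ± 9.50 CPM (-2.34 ± 0.44, adjusted p = 0.0105) and Ifit1 from 109 ± 17.9 to 22.8 ± 15.6 CPM (-2.26 ± 0.37, adjusted p = 0.00477). Hmgcs1 fell from 619.7 ± 176 to 205 ± 34.1 CPM (-1.60 ± 0.18, adjusted p = 5.08e-04). Mbp, at -0.01 ± 0.26, Gfap, at -0.13 ± 0.22, Cd74, at 0.52 ± 0.55, Snap25, at -0.59 ± 0.28, and Cd3e of T cells, at -0.04 ± 0.59, did not pass.

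Cholesterol synthesis genes fell from first peak to chronic in 20 of 24 (23 adjusted over the list alone, camera adjusted p = 5.84e-27), with Idi1 (-1.82 ± 0.20), Fdps (-1.69 ± 0.21) and Cyp51 (-1.69 ± 0.17). Type I interferon genes fell in 12 of 23 (23 adjusted over the list alone, camera adjusted p = 5.31e-17). Mature oligodendrocyte genes fell in 4 of 19 (4 adjusted over the list alone, camera adjusted p = 4.51e-04), with Mobp at -0.99 ± 0.18. Disease-associated microglia genes rose in 10 of 21 (16 adjusted over the list alone, camera adjusted p = 8.77e-13), and foam cell genes in 5 of 16 (7 adjusted over the list alone, camera adjusted p = 1.33e-06), with Apoc1 at 2.62 ± 0.31. Axon injury genes rose in 5 of 11 (9 adjusted over the list alone, camera adjusted p = 7.62e-09), with Sprr1a (4.48 ± 0.73), Gal (2.5 ± 0.28), Atf3 (1.73 ± 0.32) and Ecel1 (1.68 ± 0.23). Fibroblast and matrix genes rose in 5 of 17 (11 adjusted over the list alone, camera adjusted p = 3.18e-09), with Postn (3.50 ± 0.38), Mmp2 (1.63 ± 0.25), Bgn (1.35 ± 0.26) and Fbln1 (1.27 ± 0.24). For these 7 lists adjusted p = 0.178 to 0.448 with an estimated correlation. In Schwann cell genes 0 rose and 0 fell of 10 (0 and 0 adjusted over the list alone, camera adjusted p = 0.168) (adjusted p = 0.728 with an estimated correlation). The 12 lower of the type I interferon list became 7 without first peak 2 or chronic 1 and 22 without chronic 3. The 4 lower of the mature oligodendrocyte list became 2 without first peak 1, 2 or 3. The 10 higher of the disease-associated microglia list became 6 without chronic 1. The 5 higher of the foam cell list became 8 without chronic 2.

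The comparison gave 738 genes, 493 higher and 245 lower, 325 of them by at least 2-fold. At an unadjusted p under 0.05 there were 3470. Groups did not overlap for 19.8% of genes, against 10% by chance. On the 6 libraries alone edgeR called 0 genes, with 1872 at an unadjusted p under 0.05. DESeq2 called 1529 and library weights, added after the counts were seen, 5011, of which 616 and 2882 were lower. Without first peak 1 or 2 the count was 355 and 289, and without chronic 1, 2 or 3 it was 304, 1108 and 2084. The 245 lower genes became 89, 63 and 138 without first peak 1, 2 or 3 and 83, 396 and 1089 without chronic 1, 2 or 3. Camera called 9 lists higher and 14 lower, 0 with an estimated correlation. Fry called 9. Without chronic 3 camera called 24 lists, of which 16 were among the 23. The camera call ended for the mature oligodendrocyte list without chronic 3 (adjusted p = 0.0842), and without that library also for the complement, Fc receptor and lysosome, pan-neuronal, ion channel, inhibitory transmission and glutamatergic lists.

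**Figure D3:**
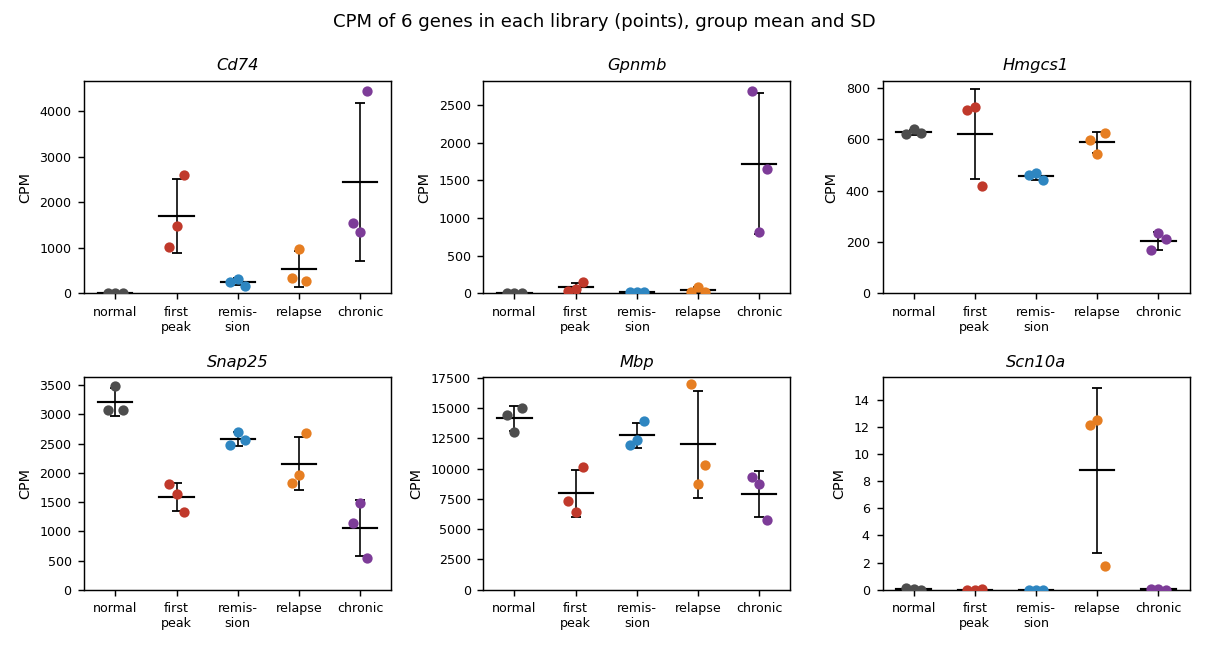
CPM of Cd74, Gpnmb, Hmgcs1, Snap25, Mbp and Scn10a in each library by group, with the group mean and SD, on axes from 0. Gpnmb is highest in the chronic libraries, Hmgcs1 lowest there, and Scn10a lies near 0 outside relapse.

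**Figure D4:**
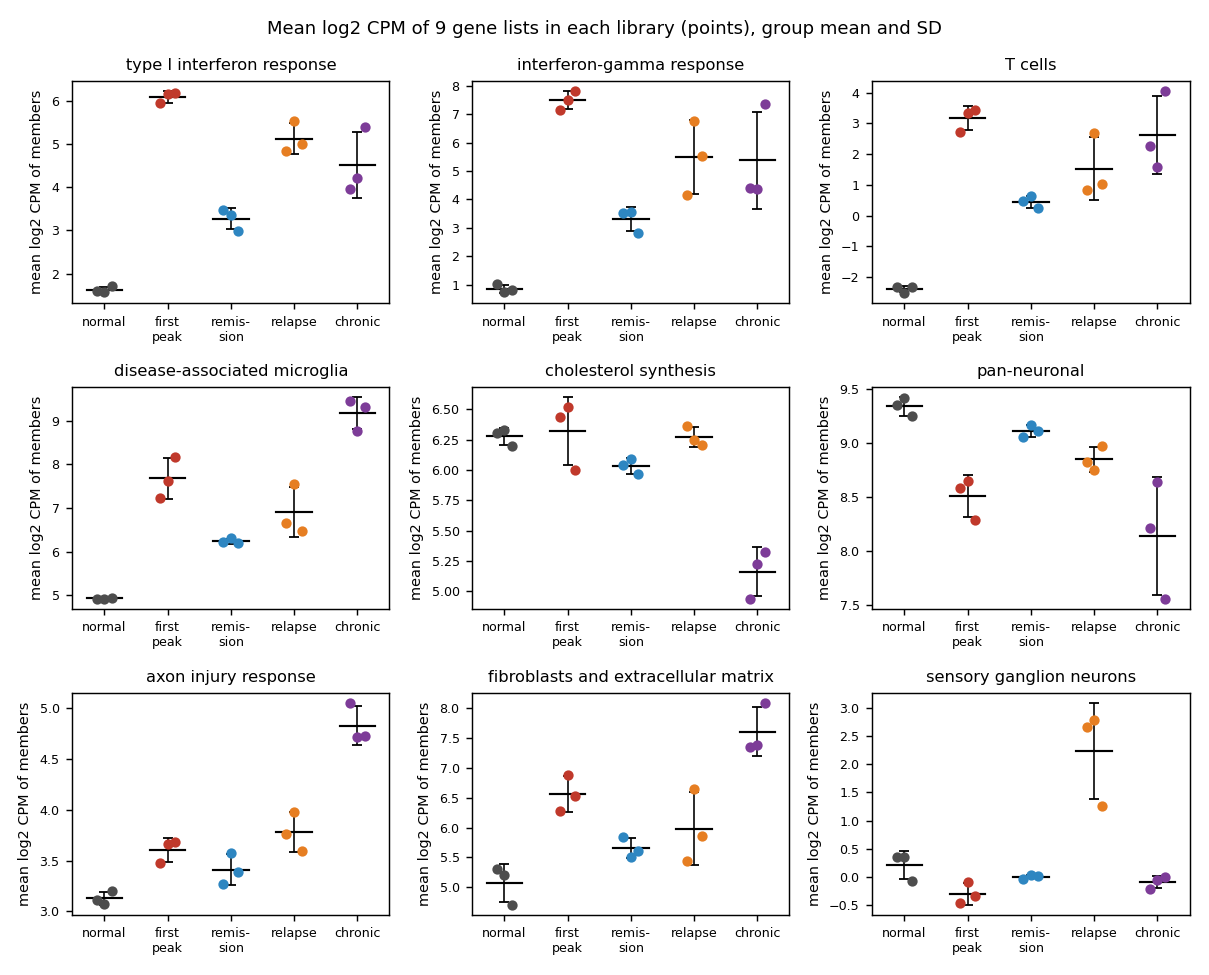
Mean log2 CPM of 9 gene lists in each library by group, 1 point per library, with a line at the group mean and a bar of 1 SD. Sensory ganglion genes stand higher in the 3 relapse libraries than in the other 12, and the relapse and chronic points are spread for the interferon-gamma list.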

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

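All tests given here, of the difference between both attacks and of leaving out libraries from it, were chosen after the data were seen, and so were the genes named as examples. The change from remission to relapse was set against the change from normal to first peak in an interaction contrast of edgeR's quasi-likelihood test. A total of 1169 genes differed. They stand here because the same step, from a quiet to an active phase, gave unequal changes. The change was larger in size at first peak for 1149 of them and at relapse for 20, and 208 had opposite signs. Without normal 1, 2 or 3 the count was 586, 547 and 615, and without first peak 2 or 3 it was 712 and 625. Leaving out remission 1 or 2 gave 594 and 625, relapse 1 or 3 gave 677 and 582, and relapse 2 gave 1969.

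Past the threshold, 20 of 23 type I interferon genes had the smaller step at relapse, with a median log2 difference of -2.45 over the list. The same held for 14 of 16 MHC class I genes (median -4.24), 10 of 11 class II genes (-4.83) and 13 of 16 T cell genes (-5.72). So it did for 13 of 16 complement genes (-2.86) and 12 of 15 Fc receptor and lysosome genes (-2.55). It held for 11 of 18 interferon-gamma genes (-4.27), 5 of 14 monocyte and macrophage genes (-4.31) and 3 of 13 cytotoxic cell genes (-5.70). It held for 2 of 16 foam cell genes (-1.28), 1 of 14 neutrophil genes (-3.76), 1 of 12 T helper genes (-2.90) and 0 of 19 cell cycle genes (-1.94). Of 14 chemokines (-2.37) 5 had a negative difference past the threshold, and among them Cxcl12 changed by 0.48 and then -0.54 (difference -1.01 ± 0.23). A low number called beside a median of this size does not show a small difference, and the lists were not tested against each other. Medians of lists with members near 0 counts in normal rest on fitted values that depend on the prior count. Such lists are T cells and cytotoxic cells, of which 1 of 16 and 0 of 13 genes reached 1 CPM in normal. Others are T helper genes with 2 of 12, chemokines with 3 of 14, monocytes and macrophages with 4 of 14 and neutrophils with 7 of 14. Cd74 changed by 7.54 and then 1.08 (difference -6.46 ± 0.85). Csf3r, the receptor of the granulocyte growth factor, changed by 3.74 and then 0.48 (difference -3.27 ± 0.34). Of the 8 sensory ganglion genes Scn11a, Scn10a and P2rx3 had the larger step at relapse, and Calca, which changed by -2.19 and then -0.05, the smaller one. Remission was not at the normal level, with Cd74 at 250.1 CPM against 9.10, so the later step began from a raised level. The contrast compares steps, not the heights of both attacks.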

How the results depend on the processing

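Only the fits with sample weights and with a Schwann cell covariate were chosen after the counts were seen. Leaving single libraries aside, 106 recomputed counts of genes or lists stayed within 1.5 times and 38 did not. The cause was not tested except where stated. No called change of a named gene turned its direction under the settings run for single genes. With library size only, with RLE size factors and with the replicate block all 209 kept their side of the threshold. DESeq2 ended 2 calls and added 3, limma-voom ended 11, sample weights ended 1 and added 9, and the covariate added 1. The 6 libraries alone ended 48 and added 3. Leaving out single libraries ended 19 calls and added 1.

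DESeq2 gave 1205 genes for remission against normal, 718 for relapse against remission, and 1421 for relapse and 1529 for chronic against first peak. Limma-voom gave 167, 71 and 1 for the first 3 of these. Limma-trend on the deposited log2 CPM gave 875 for remission against normal, and edgeR without the low-count filter 5 for relapse against first peak. With only the 6 libraries compared, edgeR gave 4343 for remission against normal and 59 for chronic against relapse. It gave 0 for relapse and for chronic against first peak, with 3846 and 1872 genes at an unadjusted p under 0.05. That setting replaces the spread pooled over 15 libraries by the spread of 6. A further requirement of at least 2-fold, fewer by construction, left 2934 genes for first peak and 4029 for chronic against normal. It left 2189 for remission against first peak, 1201 for chronic against relapse and 325 for chronic against first peak. Sample weights gave 4559 and 4343 genes for remission and relapse against normal, 9773 for remission against first peak and 1268 for relapse against remission. They gave 1489 for relapse and 5011 for chronic against first peak, and the lowest weights were 0.111 for chronic 3 and 0.239 for relapse 1. A Schwann cell covariate gave 893 genes for relapse against first peak.

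With the replicate number as a block, relapse against remission gave 106 genes, 98 of them shared with the 185, and all other totals stayed within 1.5 times. The lower genes alone moved further, from 244 to 138 for relapse and from 6 to 3 for remission, both against normal. The numbers do not pair the samples. Over 30 pairs of same-numbered libraries the correlation of deviations from the group means ran from -0.636 to 0.375, and 7 were above 0.1. The median was -0.003, against 0.026 for other pairs.

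Leaving out 1 library gave 6319 to 7980 genes for first peak, 99 to 265 for remission, 1262 to 2552 for relapse and 8271 to 9942 for chronic, all against normal. It gave 3380 to 5617 for remission against first peak, 11 to 276 for relapse against remission and 1708 to 6062 for chronic against relapse. Relapse and chronic against first peak ranged over 0 to 1229 and 289 to 2084. Camera called 33 to 34, 30 to 33, 33 to 35, 32 to 34, 29 to 32, 29 to 33, 20 to 26, 25 to 31 and 21 to 25 lists in the same order, of which at least 33, 28, 32, 32, 28, 27, 18, 24 and 16 were among those called with all libraries. With an estimated correlation camera called 0 lists in all 9 comparisons, with a lowest adjusted p of 0.178 and 1 to 15 lists at an unadjusted p under 0.05. Fry called 32, 20, 28 and 34 lists for first peak, remission, relapse and chronic against normal. It called 26 for remission against first peak and 17 for chronic against relapse. Its counts were furthest from those of camera with 10 for relapse against remission, 6 for relapse and 9 for chronic against first peak. Other scalings moved the median gene by at most 0.056 on the log2 scale. Depth limits low genes, where a floor of 3 counts applies.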

Other observations

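The tests of the 3 patterns weighed here were chosen only after the results were seen, apart from the shuffles of nerve root content. The splits of libraries were set before their results were seen. Genes of lymphoid organisation were higher in chronic than in normal cord in 9 of 12 (10 adjusted over the list alone, camera adjusted p = 1.21e-04) and plasma cell genes in 6 of 7 (6 adjusted over the list alone, camera adjusted p = 0.00258). Of the T cell inhibitory receptor genes 10 rose and 1 fell of 11 (10 and 1 adjusted over the list alone, camera adjusted p = 3.84e-04). For these 3 lists adjusted p = 0.345 to 0.369 with an estimated correlation. Cxcl13 (gene ID 55985, chromosome 5, 95956939 to 95961068), the chemokine that draws B cells into lymphoid follicles, stood at 0.101 ± 0.0634 CPM in normal and 73.2 ± 66.5 in first peak. It stood at 17.3 ± 6.17 in remission, 84.8 ± 24.9 in relapse and 148 ± 122 in chronic libraries, with an edgeR adjusted p of 1.46e-05 for chronic against normal. In the normal cord 4 of the 12, 3 of the 7 and 6 of the 11 genes reached 1 CPM. 

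Oligodendrocyte precursor genes rose from relapse to chronic in 7 and fell in 1 of 16 (8 and 1 adjusted over the list alone, camera adjusted p = 0.0945, adjusted p = 0.590 with an estimated correlation). Gpr17, a receptor of cells about to become oligodendrocytes, rose from 75.3 ± 34.4 to 199 ± 41.1 CPM (1.40 ± 0.32, adjusted p = 0.0104). The 7 higher of the oligodendrocyte precursor list became 3 without relapse 2, 1 without relapse 3 and 4 without chronic 1. The 1 lower of the oligodendrocyte precursor list became 0 without relapse 1, 2, 3 or chronic 3. In remission, brain endothelium genes were higher than in normal in 5 of 14 (12 adjusted over the list alone, camera adjusted p = 1.65e-10) (adjusted p = 0.345 with an estimated correlation). Among them Flt1 rose from 59.7 ± 11.3 to 138 ± 1.55 CPM (1.2 ± 0.15, adjusted p = 0.00167). In the normal cord 16 of the 16 precursor and 14 of the 14 endothelium genes reached 1 CPM. The 5 higher of the brain endothelium and barrier list became 1 to 2 without any of the 6 libraries. Neutrophil genes had mean log2 CPM of 4.58, 3.19 and 4.88 in first peak libraries 1, 2 and 3, 1.65, 4.34 and 1.68 in the relapse libraries and 0.53, 0.50 and 3.02 in the chronic ones.

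Some sensory neuron genes stood higher in each relapse library than in the other 12: Scn10a had 685 counts in relapse against 8 elsewhere, Scn11a 369 against 39 and P2rx3 487 against 634. In all 18 genes separated relapse in this way. Chance would give 35.9 if all libraries were exchangeable, but the groups differ in many genes, so this number cannot judge the 18. A candidate explanation is RNA of sensory neurons in the relapse samples, which stays open: over a further list of 23 ganglion genes 7 had most of their counts in relapse, such as Mrgprd with 95 of 96, but 2 of the 7 had no more than 3 counts in all, and 7 lies between the bounds set for and against it. For sensory ganglion tissue 17.4% of that list was higher in each relapse library, under the 25% set as the bound, but the exact binomial interval of 4.95 to 38.8% holds the bound, and 13 of the 23 genes had at least 0.2 CPM elsewhere, so the tissue stays open too. The abundant ganglion transcripts Calca, Prph, Sncg and Tac1 had a median difference from remission of -1.9 CPM against 8.80 ± 3.51 for Scn10a. Their differences were -0.607 ± 3.18, -3.20 ± 3.61, -4.22 ± 6.99 and 1.575 ± 0.778 CPM (± SE), each below the gain of Scn10a by more than its SE. No gain as large as that of Scn10a was seen in them, which does not decide on ganglion tissue. Prph is also in the motor neuron list, which camera put lower in relapse than in remission (adjusted p = 0.0174). That call ended without relapse 1 (adjusted p = 0.0790) or remission 2 (adjusted p = 0.0616). A fall of such cord transcripts could hide a gain. No ganglion profile was measured here, and the remission levels of these transcripts, 17.4 to 63.5 CPM, can hide a smaller share, so the tissue is not excluded. The relapse phase itself, with 3 of 8 members of the sensory ganglion list higher in each relapse library, cannot be told apart from tissue taken with the cord, since all samples of the phase carry the signal.

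Cholesterol synthesis genes were lower in the chronic libraries than at first peak. For this step, loss of neurons, oligodendrocytes or astrocytes as the whole cause is argued against by the upper quartile of the list, -0.833. It lay below the medians of pan-neuronal and mature oligodendrocyte genes, -0.35 each, and of homeostatic astrocytes, 0.13. The reference matters, since pan-neuronal genes had already fallen at first peak against normal (median -0.78), and cholesterol genes had not (0.03). From normal to chronic the cholesterol median of -1.13 was close to the pan-neuronal one of -1.08. These medians alone do not argue against loss of neurons for that longer change. Its oligodendrocyte and astrocyte medians were -0.77 and -0.50. In chronic libraries 1, 2 and 3 pan-neuronal genes had mean log2 CPM of 8.215, 8.639 and 7.558, and cholesterol genes 4.94, 5.225 and 5.327. In first peak libraries pan-neuronal genes were at 8.582, 8.648 and 8.29, and cholesterol genes at 6.439, 6.523 and 6.002. Cholesterol genes did not follow the neuronal ones, which argues against loss of neurons as the whole cause. For the step from first peak to chronic, a single chronic library is argued against, since at least 19 members were called lower without each of the 3. Lipid handling by phagocytes may contribute, as the foam cell and lipid efflux list had a median of 1.05, but whole tissue holds both lists and the cells cannot be told apart. This remains a hypothesis from the data that raised it.

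The relapse libraries spread more than the first peak ones, and depth is argued against by their totals, which lie within 1.07 times of each other. Nerve root content was not borne out and is not excluded: with the Schwann cell list as a covariate the count for relapse against first peak rose from 3 to 893 genes, and 4 of 40 shuffles of its scores within groups gave as many, none with the relapse scores in place, while the 5 shuffles that left these in place and moved those of other groups gave at most 1 gene. By the criteria set before the result was seen, nerve roots needed a count above all shuffles, which was missed with a highest of 4127, and the bound against them, 10% of the shuffles, was met exactly, which in 40 draws is within chance of either side. Disease severity at sampling could also differ, since the interferon-gamma list spans 2.6 on the log2 scale over the relapse libraries against 0.64 at first peak. The labels used here give no severity score that would separate it from the dissection.

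For each comparison, the 6 libraries make 10 splits into 3 and 3, which cannot give a share under 0.05, and the real split was the 1 with as many genes as observed. A mixed split takes the difference between the real groups into its spread. Low counts there are therefore built in where the groups differ, and they do not argue against chance. The highest other split gave 0 genes for first peak, remission, relapse and chronic against normal, where the real counts were 8103, 491, 2184 and 9657. It gave 0 also beside 5821 for remission against first peak, 185 for relapse against remission and 3 for relapse against first peak. For chronic against relapse it gave 116 beside 4485, with relapse 1 next to chronic 1 and 2. For chronic against first peak it gave 320 beside 738, with first peak 1 next to chronic 1 and 2.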
